A study of Homo sapiens with 4 samples.

How the data were processed

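RNA was measured in 4 samples: the BCR-ABL1-positive leukemia lines BV-173 and SUP-B15, each untreated and after 16 h with 10 μmol/l STI571, with 1 array per group. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit, labelled with biotin and processed by standard Affymetrix methods. The submitters' processing notes name GCOS 1.3, the scanner software of that maker. The deposited values are signal intensity per probe set on a linear scale. The way probes were summarised and the scaling target are not given in the sources used here; the 2%-trimmed mean of each deposited column was 500.2, so the authors' values had been scaled array by array. All values were above 0 and none had been logged or centred. Detection calls were not used here, so a dim signal could not be set against a stated background.

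Of 22277 probe sets, 62 were controls. The platform annotation gave 1 gene symbol for 19064 of the others, several for 1043 and none for 2108; only probe sets with 1 symbol were used. Of these, 19052 matched the RefSeq annotation of GRCh38.p14 by Entrez ID, and 0 symbols needed an update. That annotation served for names alone, and no coordinates are given. A further gene fixed in advance is not reported here.

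Signals were compared on the deposited scale as log2(signal + 24.5), the added value being the 25th percentile of all signals. A probe set was kept if it reached its array's 50th percentile in at least 1 array, and the brightest kept probe set stood for a gene, which left 7916 of 11963 genes. Where a called gene had another kept probe set, the second brightest moved in the same direction on average in 101 of 106 genes (95.3%), against 1614 of 2521 uncalled genes (64.0%). Among the genes named, the second probe set went the other way on average for EFEMP1, GPM6B, RBMS1, MKI67, RRP12, IGKC, DNAJB9, HSF1, HLA-DOA, EPOR and IRF4, of which 0 were called for STI571. Some probe sets, such as those used for CD24, CISH, CASP1 and MT1H, carry the maker's mark for probes shared with other transcripts.

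The shared effect of STI571 and the difference between the lines came from 1 limma fit (limma 3.58.1 in R 4.3.3) to all 4 arrays, with cell line and treatment as terms, moderated variances with an intensity trend and Benjamini-Hochberg adjustment at 0.05 over 7916 genes. The cell line pairs each treated array with its untreated partner, as the labels give it. This fit leaves 1 residual degree of freedom and its prior degrees of freedom were estimated as infinite, so each gene's error is the trend's value at its brightness and not its own spread. All tests were two-sided. Responses of single lines and their difference are values without a test, counted at 2-fold and 4-fold. Gene lists of at least 5 measured genes were tested with camera (preset correlation 0.01; also with an estimated correlation and on ranks), and each list's median per line was placed among 10000 random lists matched on mean level in 20 bins. The lists covered STAT5, ERK and FOXO responses, MYC and ribosome biogenesis, mitosis, replication, mismatch repair and base excision, E proteins with other transcription factors, aberrant hypermutation targets, the pre-B cell receptor, immunoglobulins, B lineage identity, the BCL2 family, p53, glycolysis, amino acid and endoplasmic reticulum stress, cholesterol synthesis, heat shock, interferon, NF-kB, MHC class II, adhesion, and markers of 5 other blood cell types.

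The genes named were set by rule before the data were examined: the 10 largest mean rises and 10 largest falls among genes at least 2-fold changed in both lines, the 5 largest each way per line, the 5 furthest apart each way in response, the 10 largest called line differences each way, up to 4 members per list with the largest mean change, and a fixed set of genes of BCR-ABL1 signalling and B cell development. Probe sets of several genes and sex chromosome markers were left out. Groups, lists, tests and most alternatives were also fixed then. The alternatives were quantile normalization, a common median, a pseudocount of 1 or of 98, no filter, a filter at the 75th percentile, the mean of a gene's probe sets, gene-specific probe sets alone, no block for the cell line (or no treatment term), no intensity trend, and thresholds of 1.5-fold and 3-fold. Added after seeing the data were a robust prior, leaving out the dimmest 25% of genes, a count of called genes that also changed 2-fold in both lines, and an exchange of the SUP-B15 labels as a check. That exchange was first run with the prior as limma fitted it and then, once its result was seen, with the infinite prior of the STI571 fit; both results are given.

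The fit for the shared STI571 effect was tested on 10 simulated data sets of 7916 genes with the arrays' own means and the trend's spread, in which 200 genes were changed by known amounts. It recovered 47.7% of the 2-fold and 81.2% of the 4-fold changes. Of its calls, 11.0% on average (5.38% to 17.1%) were unchanged genes, above the nominal 5% and above the limit first set for this check, which was then widened; with each gene's spread known the share was 5.71%. Of 168 such false calls 117 lay among the dimmest 25% of genes, and among the brighter genes the share was 4.16%. A list of 20 genes shifted by 0.5 was called in 10 of 10 data sets and an unshifted list in 0. The simulated genes varied independently of each other, so this result does not bear on false calls of lists whose genes are correlated. Each simulated gene also had exactly the trend's spread. The shares of false calls, among brighter genes too, therefore do not bear on genes whose own spread differs from the trend. Figures were drawn with matplotlib 3.10.9.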

Results

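Gene expression was measured with oligonucleotide arrays in BV-173 and SUP-B15, human leukemia cell lines that carry the Philadelphia chromosome and so express the BCR-ABL1 fusion kinase. Each line was profiled untreated and after 16 h with 10 μmol/l STI571 (imatinib), an inhibitor of that kinase. The 4 groups held 1 array each, so there were no replicates, and the number of arrays limits the precision of every value below. Each array gave a signal intensity for 22277 probe sets. The median signal was 95.5 in untreated BV-173, 107.6 in treated BV-173, 115 in untreated SUP-B15 and 106.6 in treated SUP-B15. Across probe sets, log2 signals of the untreated and treated arrays correlated with r = 0.949 in BV-173 and r = 0.952 in SUP-B15, and arrays of different lines with r = 0.898 to 0.905; probe sets are not independent replicates. After probe sets were reduced to 1 per gene, 7916 genes were compared. Changes are differences of log2(signal + 24.5), which understate the change of dim genes.

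The 3'/5' ratios of control probe sets were similar in all arrays, and 1 array, treated BV-173, stood apart in 18S ribosomal RNA. The ratio of the 3' to the 5' probe set of GAPDH, which rises as RNA degrades, was 1.16 in untreated and 1.20 in treated BV-173, and 1.12 in untreated and 1.19 in treated SUP-B15. The same ratio for ACTB lay between 2.08 and 2.40. Mean signal of the 18S ribosomal RNA control probe sets was 2817 in treated BV-173, against 1596 in untreated BV-173, 1577 in untreated SUP-B15 and 1513 in treated SUP-B15.

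The first comparison asked which genes responded to STI571 on average over both lines. DUSP6, a phosphatase that is induced by ERK and switches it off, fell furthest, from a signal of 3263 to 26.8 in BV-173 and from 9305 to 172 in SUP-B15, which is 64.1-fold and 47.5-fold on the log2(signal + 24.5) scale. Its treated signal in BV-173 lay near the added 24.5, so the size there depended on it: the log2 change of −6.0 became −6.88 with a pseudocount of 1 and −4.75 with a pseudocount of 98. With the mean of probe sets it was −4.81, the second probe set giving −4.56. ETV5, a transcription factor downstream of ERK, fell by 2.27 on the log2 scale (SE 0.30), with changes of −2.10 in BV-173 and −2.45 in SUP-B15. HBEGF, a ligand of the EGF receptor, fell by 2.09 (SE 0.36) and the glycine-cleaving enzyme GLDC by 2.19 (SE 0.32), in both lines. BCL6, a transcriptional repressor of B cells, rose 9.69-fold in BV-173, from 531 to 5357, and 3.63-fold in SUP-B15, from 684.5 to 2551; its second probe set gave log2 changes of 2.60 and 0.75. The phosphatase PTPRK rose by a mean log2 change of 1.82 (SE 0.23) and the histone gene H2AC6 by 1.93 (SE 0.31), also in both lines.

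In all, limma called 239 of the 7916 genes for STI571 at an adjusted p under 0.05, 111 of them higher and 128 lower after treatment. The responses of both lines had the same sign for 233 of the called genes and opposite signs for 6. The test is of the mean of both responses, so it favours genes with equal signs. A call therefore does not show that each line responded. Of the called genes, 36 changed at least 2-fold in the same direction in both lines, 11 upward and 25 downward, 139 did so in 1 line only and 64 stayed under 2-fold in both. With 1 residual degree of freedom the fit took its spread wholly from the intensity trend over genes. Without that trend 0 genes were called (658 at an unadjusted p under 0.05), and without the cell line as a block 0 were called (70 at an unadjusted p under 0.05). The fit without the block counts the difference between the lines, called for 2273 genes, as spread. Its loss of calls therefore does not bear on the paired changes.

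**Figure D1:**
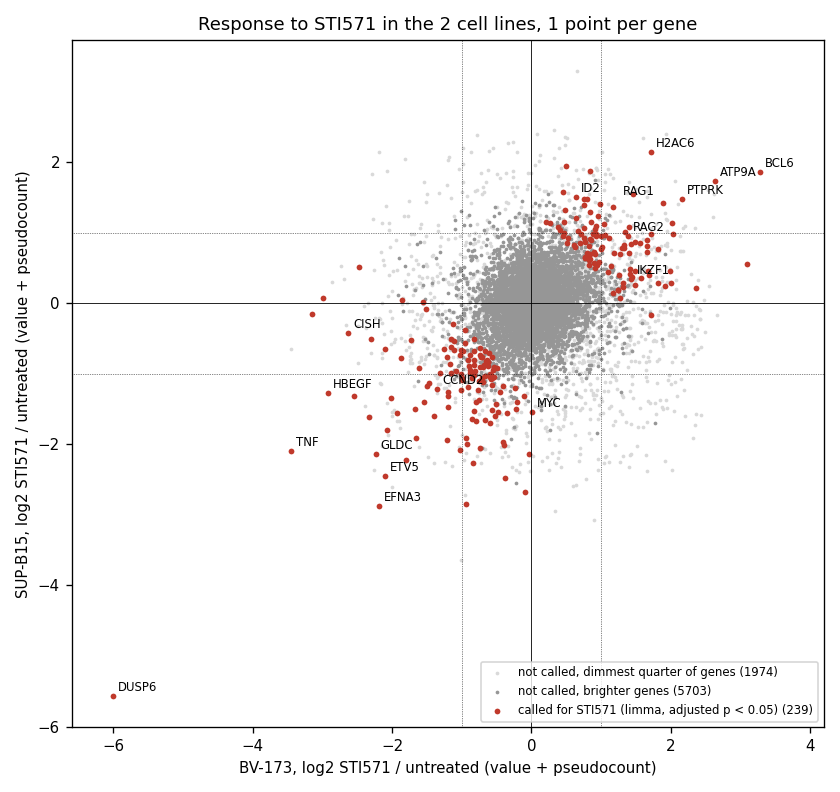
Each point is 1 of 7916 genes, with its log2 change after STI571 in BV-173 on the horizontal and in SUP-B15 on the vertical axis; red points are the 239 called genes, light grey points the uncalled genes among the dimmest 25%, and dotted lines mark 2-fold. DUSP6 lies alone at −6.0 and −5.57, BCL6 at 3.28 and 1.86.

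Among the 10 genes with the largest mean rise of those at least 2-fold higher in both lines, BCL6, ATP9A, H2AC6 and PTPRK passed the test. ATP9A, a phospholipid flippase, went from 3.6 to 149.8 in BV-173 and from 79.1 to 318 in SUP-B15 (adjusted p = 0.021). The other 6, ST7L, CYP27A1, AGAP2, ABCA1, LPO and OXT, had mean log2 changes of 1.90 to 2.16 but adjusted p-values of 0.132 to 0.586, and each started from a signal of 38.0 or less. Of the 10 largest falls, DUSP6, the cytokine TNF, the ephrin EFNA3, ETV5, GLDC and HBEGF passed. TNF went from 337 to 8.4 in BV-173 and from 131 to 11.9 in SUP-B15 (adjusted p = 0.0147), and EFNA3 from 154 to 14.8 and from 300.4 to 19.9 (adjusted p = 0.0157). ATP9A, TNF and EFNA3 are 3 of the 5 called genes among the dimmest 25%, where 117 of 168 false calls of the simulated data lay. SIGLEC15, PC, EMP1 and MFAP2 had mean log2 changes of −2.33 to −2.08 and adjusted p-values of 0.218 to 0.286; with no filter SIGLEC15 (0.0407), PC (0.0309) and EMP1 (0.0362) passed.

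The genes chosen before the data were examined included further B cell and kinase-response genes. RAG1 and RAG2, which encode the recombinase that assembles antigen receptor genes, rose in both lines, RAG1 by log2 changes of 1.89 and 1.42 (SE of the mean 0.22) and RAG2 by 1.39 and 0.95 (SE 0.29). ID2, an inhibitor of E proteins, rose by 0.64 in BV-173 and 1.5 in SUP-B15 (adjusted p = 0.000335). Its second probe set gave 1.55 in BV-173 and 1.59 in SUP-B15. IKZF1, which encodes the lymphoid factor Ikaros, rose by 1.44 and 0.34 (adjusted p = 0.00286), a call that ended with gene-specific probe sets alone (adjusted p = 0.391), with a common median (0.0834) and with the mean of its probe sets (0.439). The D-type cyclin CCND2 was called lower, with log2 changes of −1.35 and −1.22 (SE 0.28); its second probe set gave −1.02 in BV-173 and 0.26 in SUP-B15, and the call ended with the mean of its probe sets (adjusted p = 0.467). CISH, a feedback inhibitor induced by STAT5, was called lower with log2 changes of −2.63 in BV-173 and −0.42 in SUP-B15 (adjusted p = 0.00242). MYC was called lower (adjusted p = 0.02) on the strength of SUP-B15 alone, where it went from 8187 to 2805, while BV-173 gave 25862 and 26044 (log2 change 0.01); this call ended with no filter (adjusted p = 0.109) and with the mean of probe sets (0.223). PIM1, a kinase gene driven by STAT5, had log2 changes of −1.92 and −1.67 without passing the test (adjusted p = 0.0828). PAX5, BCL2L1, SOCS2, MKI67, ABL1 and BCR were not called, with mean log2 changes between −0.48 and 0.49 and adjusted p-values of 0.234 to 0.836. With the mean of probe sets, a fit whose prior degrees of freedom fell to 16.7, 15 named genes in all lost their call for STI571 (adjusted p = 0.0518 to 0.467), among them ATP9A, TNF, CISH, PA2G4, MCM4, BANK1, IGLL3P, SLC7A11 and HSPE1. TNF also lost it with a pseudocount of 1 (0.0513), PA2G4 with gene-specific probe sets (0.0861), IGLL3P with a common median (0.187), and SPRED2 with no filter (0.0967) and the 75th percentile filter (0.0689).

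**Figure D2:**
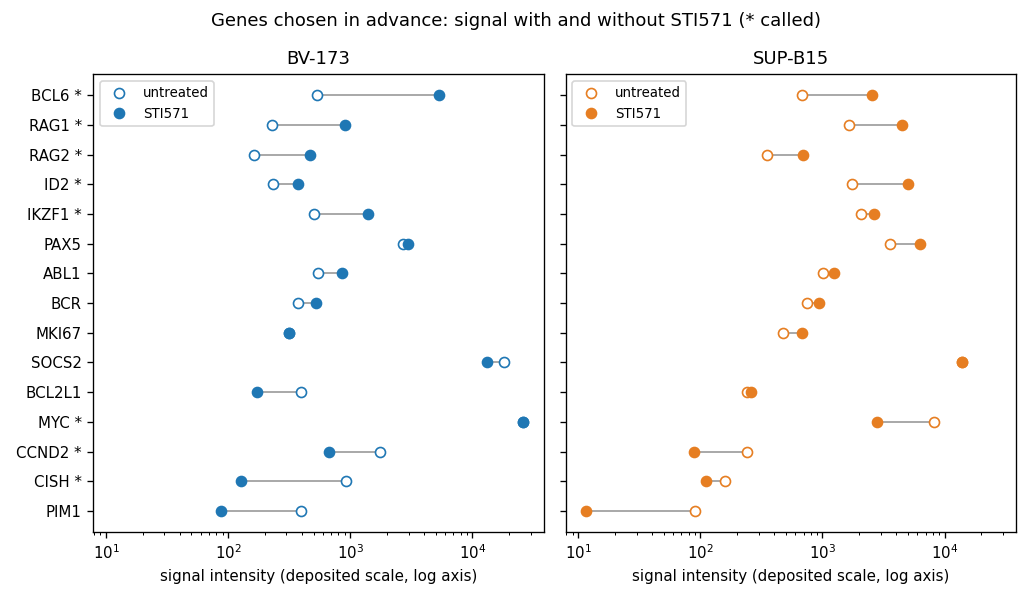
Signal intensity (deposited scale, log axis) of 15 genes chosen in advance, open circles for the untreated and filled circles for the STI571 array of BV-173 (left) and SUP-B15 (right), with 1 array per circle; an asterisk marks genes called for STI571. BCL6, RAG1 and RAG2 lie to the right after treatment in both lines, CCND2 and CISH to the left, and MYC moves from 8187 to 2805 in SUP-B15 only.

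Gene lists fixed in advance were then tested with camera for a shift against all other genes. Of 27 lists, 25 had at least 5 measured genes and 12 were called, 6 upward and 6 downward. The lists overlap, so their calls are not separate findings. BCL6 is in the STAT5, FOXO and hypermutation lists, and MYC in the STAT5, ERK and hypermutation lists. RAG1 and RAG2 are in the FOXO and pre-B cell receptor lists, and CD79B in the pre-B cell receptor and hypermutation lists. These calls used a preset correlation of 0.01 between genes. With the correlation estimated from the arrays, 0 lists were called and the smallest unadjusted p was 0.0747. Adjusted p was then 0.634 for 11 of the 12 lists and 0.833 for the mitosis list. That setting also gives camera 1 degree of freedom, so a list needs a far larger statistic to pass. The ERK feedback list's estimate was 0.011, near the preset, yet its unadjusted camera p went from 1.69e-17 to 0.0747. Estimates for the hypermutation and adhesion lists were negative. Correlation therefore does not explain the loss of these 3 calls. For the other lists the setting cannot tell correlation from the lost degrees of freedom. On ranks 8 of the 12 were called, and without the intensity trend 8.

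Genes of the ERK pathway's feedback and immediate early response fell as a list (camera adjusted p = 4.22e-16, adjusted p = 0.634 with an estimated correlation, and 0.0107 on ranks). Their median mean change was −0.82, and −0.25 with no filter. A negative change in both lines was found for 7 of 14, and a positive one in both for 1. Of 14 measured genes, 6 were called lower, 1 higher and 7 neither; adjusted over the list alone the counts were 6 and 1. Beside DUSP6 and ETV5, the ERK inhibitors SPRED2 (log2 changes −1.62 in BV-173 and −0.92 in SUP-B15) and SPRY2 (−0.82 and −1.53) fell. The exception was DUSP1, a phosphatase gene of the same family as DUSP6, named after its value was seen, with 1.91 and 0.24. Target genes of STAT5, a transcription factor activated by BCR-ABL1, were not called as a list (adjusted p = 0.155), though they were called downward with a common median (0.0214) and with the mean of probe sets (0.0407), in a range of 0.0214 to 0.716 over the alternatives; of 16, 4 were called lower and 1, BCL6, higher, and adjusted over the list alone 5 were lower and 1 higher. The list did not separate genes that STAT5 induces from genes that it represses, and members moving in opposite directions offset each other in the test. The lymphotoxin gene LTB was among the STAT5 targets called lower, at −0.93 and −1.99. FOXO target genes rose as a list (camera adjusted p = 1.14e-06, adjusted p = 0.634 with an estimated correlation, and 0.143 on ranks), with 6 of 18 called higher and 1 lower, over all genes and adjusted over the list alone. BCL6, RAG1 and RAG2 led them, and the exception, TRIB1, had −0.50 and −1.43.

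Pre-B cell receptor and V(D)J recombination genes rose as a list (camera adjusted p = 1.6e-09, adjusted p = 0.634 with an estimated correlation). Of 18 measured genes 9 were called higher and 1 lower, with the same counts adjusted over the list alone. CD79B, the signalling chain of the B cell receptor, had log2 changes of 1.66 in BV-173 and 0.72 in SUP-B15, and VPREB3 1.35 and 1.01. VPREB1, a part of the surrogate light chain, BLNK, the adaptor of pre-B receptor signalling, and DNTT, the template-independent polymerase of V(D)J joining, were also called higher; they were singled out after their values were seen, and had 2.01 and 0.28, 1.67 and 0.45, and 1.69 and 0.40. The gene called lower was BANK1, an adaptor of B cells, with −0.09 and −2.68. B lineage identity genes also rose (camera adjusted p = 5.67e-07, adjusted p = 0.634 with an estimated correlation, and 0.112 with gene-specific probe sets alone), 8 of 20 called higher and 1 lower, and adjusted over the list alone 11 and 2. BACH2, a repressor of plasma cell differentiation, rose from 113.5 to 533 in BV-173 and from 851 to 1908 in SUP-B15. The surface antigen CD24 had log2 changes of 2.36 and 0.21, and the stem cell antigen CD34 1.82 and 0.77, while CD38 was not called (adjusted p = 0.091). Immunoglobulin genes were not called as a list (adjusted p = 0.242), with 1 of 9 called higher and 1 lower, and adjusted over the list alone 3 and 1; the gene called lower was JCHAIN, the joining chain of secreted antibody, at −0.40 and −1.97, and the gene called higher the pseudogene IGLL3P, at 0.52 and 0.86.

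A list of E proteins, ID proteins and other transcription factors was called upward (camera adjusted p = 0.00124, adjusted p = 0.634 with an estimated correlation, 0.174 on ranks and 0.222 without the intensity trend), with 4 of 18 called higher and 0 lower, and adjusted over the list alone 8 and 1. The progenitor transcription factor MYB, at log2 changes of 2.03 and 0.97, led them with ID2. Genes known to be mutated by aberrant hypermutation in B cell tumours were called upward (camera adjusted p = 0.000241, adjusted p = 0.634 with an estimated correlation, 0.143 on ranks and 0.168 without the intensity trend), 3 of 18 called higher and 1 lower, and adjusted over the list alone 7 and 2. BCL6 and CD79B rose, ST6GAL1 did not pass (1.99 and −0.06, adjusted p = 0.0833), and MYC was the gene called lower. In the list of mismatch repair and base excision genes 0 of 23 were called and the list was not (adjusted p = 0.359), its median being 0.02 and its mean −0.09; adjusted over the list alone 1 gene was lower. The exonuclease EXO1 had −1.05 and −0.89 (adjusted p = 0.0528) and the uracil glycosylase UNG −1.05 and −0.88 (adjusted p = 0.102).

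Genes of DNA replication and the G1/S transition fell (camera adjusted p = 5.84e-15, adjusted p = 0.634 with an estimated correlation). Of 30 measured genes 6 were called lower and 0 higher, 14 were lower adjusted over the list alone, and 27 had a negative change in both lines. CDC45, a part of the replicative helicase, fell by 2.01 in BV-173 and 1.35 in SUP-B15, GINS2 of the same helicase by 1.47 and 1.13, and the helicase subunit MCM4 by 1.09 and 0.96; E2F1, a driver of S phase entry, was not called (−1.84 and −0.11, adjusted p = 0.248). The mitosis list was called upward (camera adjusted p = 0.047, adjusted p = 0.833 with an estimated correlation) although 0 of its 30 genes were called, also when adjusted over the list alone. Its median change was 0.02 in BV-173 and 0.31 in SUP-B15, and its call ended with a common median (adjusted p = 0.0764), with the 75th percentile filter (0.096), with gene-specific probe sets (0.112), without the intensity trend (0.0913) and without the dimmest 25% of genes (0.0658). BUB1, a kinase of the spindle checkpoint, had 0.16 and 0.94 (adjusted p = 0.228).

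The 3 lists of growth and metabolic genes fell. Ribosome biogenesis and MYC target genes (camera adjusted p = 1.6e-09) had 5 of 25 called lower and 0 higher, 8 and 0 adjusted over the list alone, and a negative change in both lines for 20. PA2G4, a growth-regulated nucleolar protein gene, fell by 0.88 and 0.95 and the nucleotide kinase gene NME1 by 0.69 and 1.11. Glycolysis genes (camera adjusted p = 1.54e-10) had 5 of 18 called lower and 0 higher, and 13 lower and 1 higher adjusted over the list alone. SLC2A3, a glucose transporter, fell by 1.93 and 1.55 and the aldolase ALDOC by 0.67 and 1.65; LDHA, lactate dehydrogenase, had −0.56 and −0.89 (adjusted p = 0.0591). Cholesterol synthesis genes (camera adjusted p = 2.69e-10) had 5 of 15 called lower and 0 higher, and 10 and 0 adjusted over the list alone. HMGCS1, which makes the precursor of mevalonate, fell by 1.20 and 1.47, and MSMO1, a sterol oxidase, by 0.99 and 1.08. For each of these 3 lists adjusted p was 0.634 with an estimated correlation.

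Cell adhesion and homing genes were called downward (camera adjusted p = 0.047, adjusted p = 0.634 with an estimated correlation), although their median was 0.01 and their mean −0.33. Of 12 genes 2 were called lower and 1 higher, and adjusted over the list alone 3 and 1. The integrin genes ITGB2 (−1.80 and −2.22) and ITGA6 (−2.08 and −1.79) fell, and the chemokine receptor CXCR4 rose (0.84 and 0.91). This call ended under 10 of the 12 alternatives, with adjusted p-values of 0.0857 to 0.754.

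The remaining lists were not called. Amino acid and endoplasmic reticulum stress genes (adjusted p = 0.259) had 2 of 23 called higher, DDIT3 with 0.49 and 1.94 and the cystine transporter SLC7A11 with 0.76 and 1.40, and adjusted over the list alone 3 higher and 1 lower. Heat shock genes (adjusted p = 0.172) had 1 of 11 called lower, HSPE1 with −0.61 and −0.83, also adjusted over the list alone. This list was called downward with quantile normalization (adjusted p = 0.0466), a common median (0.0452) and the mean of probe sets (0.0138), in a range of 0.0138 to 0.712 over the alternatives. NF-kB target genes (adjusted p = 0.982) had 1 of 12 called lower, TNF, with a median of 0.06 and a mean of −0.20; adjusted over the list alone 1 was higher and 1 lower. Of 13 p53 target genes (adjusted p = 0.981; median −0.06, mean 0.02) 0 were called, and 1 was higher adjusted over the list alone. BCL2 family genes (13 measured, adjusted p = 0.548), interferon response genes (18, adjusted p = 0.433) and MHC class II genes (13, adjusted p = 0.289) had 0 called, also adjusted over the list alone.

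Of the markers of other blood cells, 5 of 18 myeloid, 6 of 16 T cell, 4 of 16 erythroid and megakaryocyte and 2 of 11 natural killer markers were measured. Signals below the filter left out 11, 9, 7 and 7 of them in that order, and 2, 1, 5 and 2 had no probe set naming 1 gene. Of the measured markers of these 4 kinds 0 were called for STI571, over all genes or adjusted over the list alone. The tested lists gave adjusted p = 0.926 for myeloid markers, with a downward direction although their median was 0.01 and their mean 0.03, and 0.611 for T cell markers. Of 6 plasma cell markers 1, JCHAIN, was called lower, also adjusted over the list alone (list adjusted p = 0.433; median 0.08, mean −0.11).

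**Figure D3:**
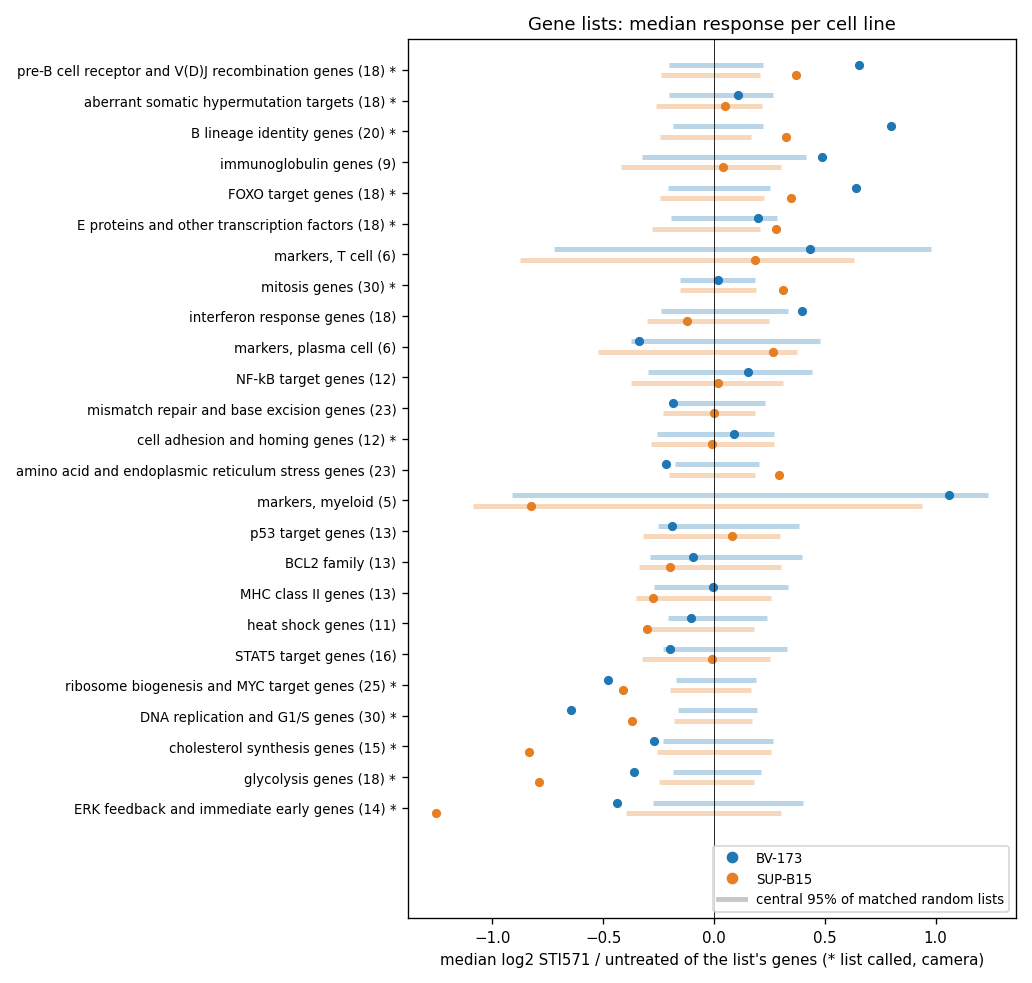
Median log2 change after STI571 of each tested gene list (number of measured genes in parentheses) in BV-173 (blue) and SUP-B15 (orange); bars span the central 95% of 10000 random lists matched on mean level, and an asterisk marks the 12 lists called by camera with the preset correlation. The ERK feedback list has medians of −0.44 and −1.26, the pre-B cell receptor list 0.65 and 0.37.

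Taken per line, the response has no test, since each rests on 2 arrays. In BV-173, 547 genes were at least 2-fold higher and 364 at least 2-fold lower after STI571, a balance that turned with a common median (457 and 482). The treated array of this line was the one with the 18S control signal of 2817. On this scale the largest increases were those of BCL6 (log2 change 3.28), the receptor gene GPR18 (3.10, from 4.9 to 228), SULT4A1 (2.66), ATP9A (2.63) and CYP27A1 (2.63); with a pseudocount of 1 all 4 others, such as GPR18 (5.28), ATP9A (5.03) and CYP27A1 (3.99), lay above BCL6. The largest decreases were those of DUSP6 (−6.0), TNF (−3.46), ARID3B (−3.45), the potassium channel gene KCNA5 (−3.15) and the replication gene GINS4 (−2.99). In SUP-B15, 323 genes were at least 2-fold higher and 450 lower, which also turned with a common median (413 and 368). IKZF2, which encodes the Ikaros relative Helios, had the largest increase (3.28, from 5.9 to 271.5), followed by MPP2 (2.45), DENND5B (2.39), ST7L (2.39) and CRISPLD2 (2.39), and DUSP6 (−5.57), SIGLEC15 (−3.64), NCALD (−3.07), HSD11B1 (−2.95) and EFNA3 (−2.87) had the largest decreases. Most of these 2-fold changes came from dim genes. Without the dimmest 25% of genes, an alternative added after the data were seen, 268 genes were at least 2-fold apart in BV-173 and 247 in SUP-B15.

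Against random lists of matched brightness, the median of the FOXO, pre-B cell receptor and B lineage lists lay at the 99.85th percentile or above in both lines. The ERK feedback list lay at percentile 0.29 in BV-173 and 0 in SUP-B15, ribosome biogenesis at 0 and 0, DNA replication at 0 and 0.01, glycolysis at 0.01 and 0, and cholesterol synthesis at 1.395 and 0. The mitosis list was at percentile 52.1 in BV-173 and 99.99 in SUP-B15. Stress genes lay at opposite ends, at percentile 0.755 in BV-173 (median −0.22) and 99.9 in SUP-B15 (median 0.30). The list of E proteins and other transcription factors lay at percentile 90.0 in BV-173 and 99.4 in SUP-B15, and the hypermutation targets, with line medians of 0.11 and 0.05, at 75.3 and 71.3, inside the central 95% in both lines. Interferon response genes were at percentile 99.2 in BV-173 and 22.8 in SUP-B15, and immunoglobulin genes at 98.9 and 75.2. These percentiles describe the 4 arrays and test no difference between the lines.

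The lines shared more changes than independent lists would. At 2-fold, 62 genes were higher in both lines, where independent lists of these lengths give 22.3, and 67 were lower in both, where they give 20.7. Opposite changes of at least 2-fold were found for 100 genes, against 45.9. Across genes the responses correlated with Pearson's r = 0.129 and Spearman's rho = 0.151, where genes are not independent replicates. Brightness separated the 2 kinds of overlap. Among the dimmest 25% of genes 91 changed in the same direction (82.4 for independent lists) and 95 in opposite directions (88.5), with r = 0.017. Among the brighter 75% 38 changed in the same direction (5.42 for independent lists) and 5 in opposite directions (5.73), and r was 0.177, 0.389 and 0.410 in 3 equal bins of them, from the dimmest to the brightest bin.

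A further comparison asked where the lines differed in their response. No test was possible with 1 array per condition, so the genes are given by size. The responses lay at least 4-fold apart for 352 genes, 319 of them among the dimmest 25%. Those furthest apart with SUP-B15 above BV-173 were IQCC, ADAP2, SERPINB13, KLHL28 and the ERK inhibitor SPRY4, by 3.46 to 4.34 on the log2 scale. With BV-173 above SUP-B15 they were COL6A1, PAGE4, C19orf73, CEACAM6 and HPGD, by differences of −4.39 to −4.05. No signal of these 10 genes exceeded 188 in any array, and their sizes depended on the added value. With a pseudocount of 98 the differences were 1.78 to 2.09 and −2.21 to −1.82, and with a pseudocount of 1 they were 5.41 to 7.75 and −8.46 to −6.28. With no filter COL6A1 gave −1.10 and SERPINB13 1.51.

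The last comparison set the lines against each other with the treatment as a covariate. EFEMP1 and SNX7 stood furthest apart, both higher in SUP-B15. EFEMP1, an extracellular matrix protein gene, gave 8693 untreated and 13888 treated in SUP-B15 against 28 and 4.7 in BV-173, a log2 difference of 8.14 (SE 0.25). SNX7 (8.13), the caveolae gene CAV1 (7.87), GPM6B (6.79), the endothelial and leukocyte adhesion gene PECAM1 (6.73), the transcription factor POU4F1 (6.65), the basement membrane gene NID2 (6.33), SLIT2 (6.08), COCH (6.05) and the kinase gene PRKCB (6.0) followed. BV-173 was higher for MYLK3, at 6968 and 9325 against 22.3 and 58.2 (−7.02, SE 0.24), LAPTM4B (−6.86), PRPS2 (−5.99), the imprinted gene MEST (−5.48), the regulator of G protein signalling RGS1 (−5.14), TUBB6 (−4.31) and LY75 (−4.30), TFEC (−4.26), RBMS1 (−4.24) and NAXD (−4.06). All 20 were called by limma. The signals of EFEMP1, SNX7, CAV1, PECAM1, NID2 and COCH in BV-173 were 28 or less, as were those of PRPS2 in SUP-B15. The size and order of such differences depended on the added value, and SNX7 lay above EFEMP1 with a pseudocount of 1.

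Limma called 2273 genes between the lines, 28.7% of those tested, 1136 higher in SUP-B15 and 1137 higher in BV-173; with a common median the split was 854 and 1234. Of 20 B lineage identity genes 13 were higher in SUP-B15 and 2 in BV-173, and of 18 pre-B cell receptor genes 12 and 4. RAG1 was higher in SUP-B15 by 2.5 (SE 0.22) and ID2 by 3.23 (SE 0.23). MYC was higher in BV-173, with a difference of −2.43 (SE 0.22), as were 16 of 25 ribosome biogenesis genes, with 0 higher in SUP-B15, and CCND2 (−2.68, SE 0.28). Of 30 replication genes 12 were higher in BV-173 and 1 in SUP-B15, and of 18 glycolysis genes 8 and 1. Each line was represented by 2 arrays that differ in treatment, and no label says that arrays came from separate cultures. The p-values set each difference against the trend's spread at that brightness. They measure neither the gene's own spread nor that between cultures. Without the intensity trend 629 genes were called, 550 of them among the 2273.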

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

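The test of scatter among dim genes was chosen only after the result was seen. Among the genes named, 12 moved at least 2-fold in opposite directions in the 2 lines after STI571, and none of these differences was tested. As SUP-B15 minus BV-173 on the log2 scale, the response was higher in SUP-B15 for IQCC (4.34), ADAP2 (4.12), SERPINB13 (3.95), KLHL28 (3.86), SPRY4 (3.46) and the T cell and natural killer gene IL2RB (3.0), and lower for COL6A1 (−4.39), PAGE4 (−4.24), C19orf73 (−4.15), CEACAM6 (−4.08), HPGD (−4.05) and the myeloid factor gene CEBPE (−2.18). SPRY4, an ERK inhibitor, went from 188 to 25.5 in BV-173 and from 10.1 to 65.3 in SUP-B15. All 12 belong to the dimmest 25% of the genes compared. The differences of IL2RB and CEBPE, the smallest of the 12, were not compared under the alternatives. With a pseudocount of 98 the differences of ADAP2 (1.98), SERPINB13 (1.78), KLHL28 (1.84), SPRY4 (1.81), PAGE4 (−1.93) and HPGD (−1.82), and with no filter those of COL6A1 (−1.10) and SERPINB13 (1.51), were too small for opposite 2-fold changes.

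Genes that moved at least 2-fold in opposite directions numbered 100, and 95% of them lay among the dimmest 25%. There, their number was 1.07 times the count that independent lists give, so scatter of dim probe sets could account for about as many as were seen. Real responses that are unrelated between the lines would give about the same count, so the ratio cannot tell them from scatter. A response particular to each line predicts that a second probe set of the gene repeats the difference, and it did for 3 of the 7 genes that have one (42.9%, exact 95% interval 9.9% to 81.6%), which decides nothing. For genes changed in the same direction in both lines, the second probe set moved with the first in 23 of 26 (88.5%, 69.8% to 97.6%). Which of the 100 genes respond differently in the lines stays open, since no condition was repeated.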

How the results depend on the processing

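The robust prior, the omission of the dimmest 25% of genes and the count of called genes at 2-fold in both lines were chosen only after the results were seen. Among the genes named, no called gene reversed direction in any alternative run for it, and no called list reversed the direction of its test. The directions of the other called genes were not compared. The median of the adhesion list did change sign with no filter (−0.11) and with the larger pseudocount (−0.03). The 239 genes called for STI571 became 153 with a common median (144 of them among the 239), 116 with the mean of probe sets (115 shared), 137 with gene-specific probe sets, where 4865 genes were tested (127 shared), 36 when a 2-fold change in both lines was also required, and, in limma, 0 without the cell line as replicate block (70 at an unadjusted p under 0.05) or without the intensity trend (658); the other alternatives gave 201 to 264. The 2273 calls between the lines became 1340 with gene-specific probe sets, 1460 without the treatment term (the fit without a block) and 629 without the trend. The 12 called lists became 0 with an estimated correlation. A common median moved the median response of all genes from 0.05 to −0.11 in BV-173 and from −0.01 to 0.09 in SUP-B15, and the share of STI571 calls that were higher from 46.4% to 38.6%. Apart from fewer genes or a stricter criterion, the cause of these changes was not tested.

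The counts without a test depended on how dim genes were treated. Genes at 2-fold in BV-173 (911) became 284 with the larger pseudocount, 1861 with no filter, 191 with the 75th percentile filter and 268 without the dimmest 25%, and 2155 at 1.5-fold and 356 at 3-fold. In SUP-B15, 773 became 251, 1727, 181 and 247 under the same settings, 502 with gene-specific probe sets, 2063 at 1.5-fold and 240 at 3-fold. Genes changed in the same direction in both lines (129) became 253 with a pseudocount of 1, 30 with the larger one, 258 with no filter, 35 with the 75th percentile filter, 38 without the dimmest 25%, 538 at 1.5-fold and 27 at 3-fold. Responses at least 4-fold apart (352) became 703, 14, 675, 27 and 33 in that order of the first 5 settings, and 230 with gene-specific probe sets. The highest GAPDH 3'/5' ratio was 1.26 after quantile normalization, against 1.20.

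Of the values of named genes, 85 were tested, and 48 lost their call without the block and 48 without the trend. Those 48 were all the STI571 calls among the 85, the rest being line differences or uncalled values. A call was lost for 15 with the mean of probe sets, 4 with a common median and 3 with no filter. It was lost for 2 each with a pseudocount of 1 and gene-specific probe sets, and for 1 with the 75th percentile filter. With quantile normalization, the larger pseudocount or the robust prior 0 lost it, and 3 gained one with no filter. Among untested values of named genes, 26 moved with a pseudocount of 1 and 27 with the larger one. Leaving out a line was not a test, because 1 line leaves no residual degrees of freedom. The dimmest genes limit what the arrays show: across genes the responses of the lines correlated with r = 0.017 among the dimmest 25% and 0.410 among the brightest.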

Other observations

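Of the tests in this part, the exchange of treatment labels was chosen in its reported form only after a result was seen. Some called genes outside the lists, singled out here after their values were seen, had large changes in at least 1 line. LPAR6, a receptor for lysophosphatidic acid, fell from 11157 to 2193 in BV-173 and from 2874 to 919 in SUP-B15. GSDME, a pore-forming gasdermin, fell from 552.4 to 157.4 and from 9508 to 3357. CASP1, the protease of inflammasomes, had log2 changes of −0.83 in BV-173 and −2.27 in SUP-B15, while CASP6 rose by 1.41 and 1.08. The phosphatase PTP4A3 fell by 1.66 and 1.91, the kinase PRKD2 by 1.54 and 1.41, and the receptor TNFRSF1B by 1.21 and 1.94. The tetraspanin CD81 rose by 0.95 and 1.23, YPEL5 by 1.56 and 0.86, the lectin-like receptor CLEC2D by 1.66 and 0.89, and the metallothionein MT1H by 0.80 and 1.47. The histone demethylase KDM5B had 1.99 in BV-173 and 0.45 in SUP-B15.

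The replication list was called downward under STI571 by camera with the preset correlation, and the mitosis list did not fall with it. With an estimated correlation the replication list was not called (camera adjusted p = 0.634), and 6 of its 30 genes were called lower. The median of the mitosis list was 0.02 in BV-173, at percentile 52.1 of matched random lists, and 0.31 in SUP-B15, which put it 0.664 and 0.680 above the median of the replication list. An intensity-dependent difference between arrays predicts that lists matched on brightness shift alike, but the replication list lay at percentile 0 of 10000 matched lists in BV-173 and 0.01 in SUP-B15. The difference of medians over both lines was 0.705, and 0.701 with quantile normalization, which decides nothing about scaling because 1 factor per array cancels from it. The difference between the lists was not tested itself, and no biological explanation was tested.

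The 239 calls for STI571 rest on a spread read from the intensity trend, and whether that spread is too small stays open. With the treatment labels of SUP-B15 exchanged, so that the fit looks for opposite responses, limma called 0 genes, or 3 with the infinite prior of the STI571 fit (323 at an unadjusted p under 0.05). Of these 3, GOLGA7 (log2 changes −2.48 in BV-173 and 0.51 in SUP-B15) and CD24 were also among the 239. The exchange decides nothing, because opposite responses are the residual from which the trend of the STI571 fit was made.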
